A study of Mus musculus with 34 samples.

How the data were processed

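Total RNA from whole, unsorted livers of mouse fetuses was hybridised to 34 Affymetrix one-colour arrays after biotin labelling. The sample labels give embryonic day 14.5 for each array, while the series design gives a span from day 13.5 to 14.5, so some spread in age between samples cannot be excluded. The authors made the values with MAS5 in GCOS 1.4, and the deposited unit is intensity, the linear MAS5 signal of each probe set. The deposited signals were not on a log scale. Their 2% trimmed means ran from 495.4 to 497.7 per array, so each array had already been scaled to a common level. No detection calls and no scan dates came with the values. For arrays, the number of arrays limits the precision.

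The file held 45037 probe sets, and no column was without a sample. Gene symbols came from the refseq gene table (GRCm38.p6), used only for names and for which genes lie near each other. 34945 probe sets matched 1 symbol, 932 matched several and were left out, and 9160 matched none. The signals were rescaled to a 2% trimmed mean of 500 and transformed to log2(signal + 32). Each of the 18193 genes was represented by its probe set with the highest mean over the 34 arrays. Genes with a signal of at least 100 on at least 2 arrays were tested, which left 12719.

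The groups were the 8 genotypes of the labels. limma was used (lmFit, contrasts.fit and eBayes with trend=TRUE, two-sided tests) with 1 mean per genotype over the 34 arrays, so that the spread between arrays was shared by all genotypes. Genotypes were compared in 11 pairs, and 1 interaction term compared the effect of Rb1 loss with and without joint p107 and p130 loss. A further additive fit had 1 term each for loss of Rb1, p107 and p130, and its Rb1 term is called Rb1 loss over all backgrounds. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The labels do not say whether arrays come from separate animals, so the p-values measure only the spread between these samples. The p107 KO group has 1 array, and its values are given without a test.

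18 gene lists were written by hand: S-phase and E2F target, G2/M, erythroid maturation, embryonic globin, hepatocyte and hepatoblast, macrophage, neutrophil and granule, megakaryocyte and platelet, stem and progenitor cell, lymphoid, endothelial, stellate and mesenchymal, hypoxia-response, p53 target, interferon-response, mitochondrial respiration, histone, and pocket protein and cell-cycle regulator genes. Of the 40 erythroid maturation genes written, 32 could be tested, as could 6 of 12 histone genes, 7 of 14 lymphoid genes and 14 of 18 p53 target genes. Each list was compared with the other genes by camera in limma with a preset correlation of 0.01 between genes, over 18 lists and 13 comparisons (234 tests adjusted together). The same tests were repeated with an estimated correlation, and fry was run beside them.

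Genes were named by a rule. It takes each probe set of Rb1, Rbl1 (p107) and Rbl2 (p130) in every genotype. For the 6 principal comparisons it takes up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean log2 signal of at least 8 and, except in the additive fit, no overlap between the arrays of the groups compared. For the others it takes up to 5 and 5, and up to 4 members of each list with the largest test statistic. Genes chosen for no overlap lie beyond the other group's mean on every array, so such counts for them follow from the rule. Genes named outside the rule are identified where they appear. The groups, comparisons, tests, lists, thresholds and this rule were fixed before the data were examined, as were the alternatives below except where stated.

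The alternatives were pseudocounts of 1 and 100, no filter on low signal, a signal of 200 or more on at least 6 arrays, quantile normalization, the mean of all probe sets of a gene, eBayes without the trend or with a robust fit, array weights, only the arrays of the groups compared, the replicate number as a block, an added 2-fold threshold, an estimated correlation, and leaving out each array in turn. After the data were seen, the arrays were clustered into 3 groups without use of genotype, a number that was set and not estimated. The clustering used the log2 difference between the 2 brightest probe sets of the same gene (2997 genes with a median signal of at least 300, differences clipped at 2). Array group was then added as a block or used to repeat comparisons within a group. These array groups were inferred from the signals and are not a recorded batch. Leaving out arrays 8 and 9 of the Rb1 and p130 double knockout, reading the additive fit for p107 loss and p130 loss, and the tests of genes near the targeted genes were also chosen after the data were seen, the test near Rb1 before its own result.

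The steps were tested on simulated data, with 100 genes changed per fold in 12719. The simulated noise was independent between genes and held no array groups, so recovery in the real data may differ. In Rb1 loss over all backgrounds 82% of 1.5-fold and 98% of 2-fold changes were recovered. In the comparison of the triple knockout with the p107 and p130 double knockout the shares were 43% and 82%, in Rb1 KO against wild type 9% and 34%, and for the interaction term 1% and 23%. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.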

Results

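The retinoblastoma family has 3 members, Rb1, p107 (gene Rbl1) and p130 (gene Rbl2), which restrain the cell cycle by binding E2F transcription factors. RNA was measured in unfractionated fetal liver, the main site of blood formation at this stage, from mice lacking combinations of the 3. The 34 arrays fell into 8 groups: 2 wild type, 1 p107 KO, 3 p130 KO, 6 p107 and p130 double knockout (p107;p130 DKO), 2 Rb1 KO, 5 Rb1 and p107 double knockout (Rb1;p107 DKO), 9 Rb1 and p130 double knockout (Rb1;p130 DKO) and 6 triple knockout (Rb1;p107;p130 TKO). The median signal per array ran from 80.6 to 115.9, and 45.6 to 53.3% of probe sets reached a signal of 100. Pairs of arrays correlated at r = 0.909 to 0.980 across genes, which are not independent replicates. Xist was detected without Y-linked genes on 17 arrays and Y-linked genes without Xist on the other 17. The sexes were unevenly spread, with 3 Xist arrays of 3 in the p130 KO and 2 Y arrays of 2 in the Rb1 KO. The p107 and p130 double knockout had 1 Xist and 5 Y arrays, the triple knockout 4 and 2. Sex was not fitted in any comparison.

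Rb1 signal was high in the groups that carry the gene and about 5-fold lower in the Rb1-deficient groups, without reaching background. On its brightest probe set it was 7435 ± 2334 (SD, n = 2) in wild type, 5860 on the p107 KO array, 6705 ± 1306 (n = 3) in p130 KO and 6341 ± 1035 (n = 6) in the p107 and p130 double knockout. It was 1516 ± 296 (n = 2) in Rb1 KO, 937.4 ± 112 (n = 5) in the Rb1 and p107 double knockout, 1389 ± 326 (n = 9) in the Rb1 and p130 double knockout and 1143 ± 277 (n = 6) in the triple knockout. The second Rb1 probe set stayed between 23.8 and 59.5 in each group mean. Rbl1 signal was 1407 ± 266 in wild type, 1535 ± 409 in p130 KO, 1382 ± 278 in Rb1 KO and 2078 ± 577 in the Rb1 and p130 double knockout. It lay near background where p107 was deleted, at 81.7 on the p107 KO array, 73.3 ± 26.9 in the p107 and p130 double knockout, 69.5 ± 18.4 in the Rb1 and p107 double knockout and 87.6 ± 29.6 in the triple knockout. A second Rbl1 probe set gave 240.1 ± 24.9 in wild type against 34.6 on the p107 KO array and 33.0 ± 20.5 in the triple knockout, and the other Rbl1 probe sets averaged 70.4 and 38.2 in wild type. Rbl2 signal was 345.1 ± 6.8 in wild type, 481.3 on the p107 KO array, 377.7 ± 84.4 in Rb1 KO and 363.9 ± 97.3 in the Rb1 and p107 double knockout. Where p130 was deleted it was lower but present, at 195.4 ± 57.4 in p130 KO, 184.2 ± 55.6 in the p107 and p130 double knockout, 206.7 ± 40.4 in the Rb1 and p130 double knockout and 187.7 ± 47.8 in the triple knockout. The second Rbl2 probe set gave 179.8 in wild type against 100.5 in p130 KO and 81.0 in the triple knockout.

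**Figure D1:**
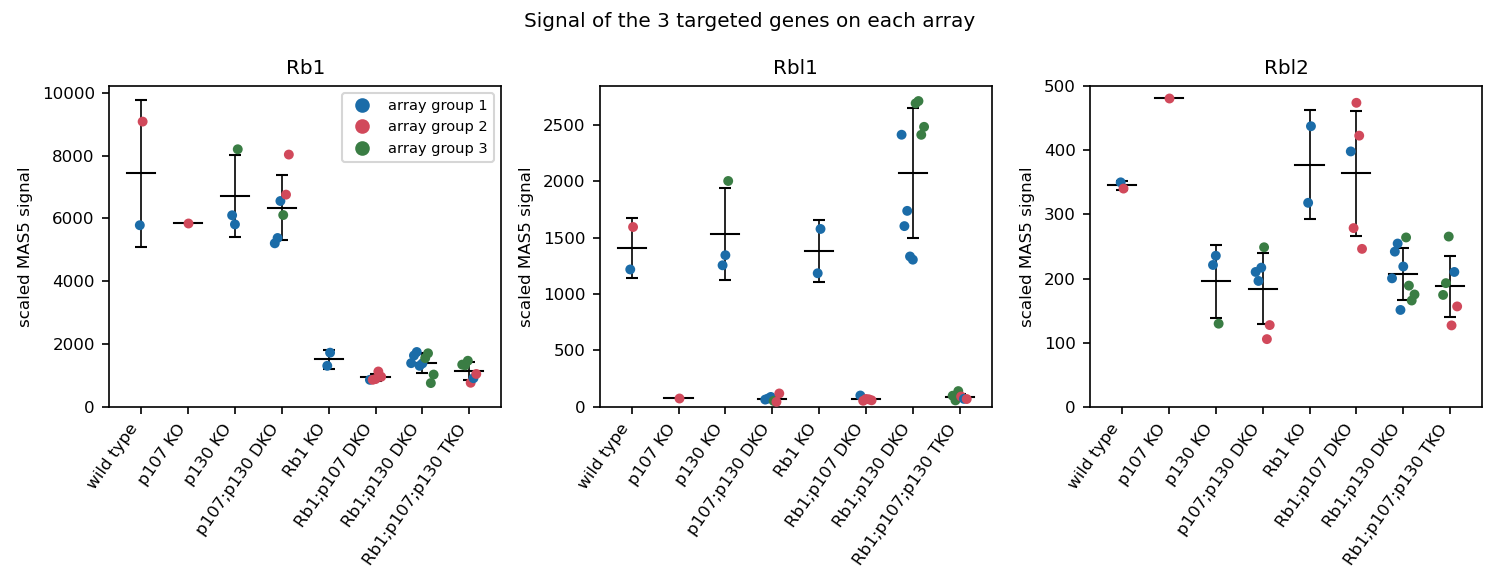
Scaled MAS5 signal (linear axis from 0) of Rb1, Rbl1 and Rbl2 on each array, by genotype. Points are arrays coloured by array group, horizontal lines are group means and error bars are 1 SD where a group has more than 1 array; Rb1 averages 1143 in the triple knockout and 7435 in wild type.

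The arrays were clustered into 3 groups of 15, 10 and 9, inferred from how strongly probe sets of the same gene reported it. The number of groups was set at 3. Some arrays fitted loosely, down to a mean correlation of 0.176 with the own group for triple knockout array 2. What sets the groups apart is not given in the labels. The first principal component of all tested genes held 16.3% of the variance and the second 14.9%. Of the variance of the first component, 89.0% lay between array groups and 23.5% between genotypes. Genotypes were spread unevenly over the array groups. The Rb1 and p130 double knockout had 5 arrays in the first, 0 in the second and 4 in the third, the Rb1 and p107 double knockout had 1, 4 and 0, and both Rb1 KO arrays were in the first. Values with array group added as a block are therefore given beside the results. Each array of the third group lacked p130, and wild type array 2 was the only array of the second that carried p107. Loss of p107 and of p130 lay 23.8% and 24.4% between array groups, against 2.7% for Rb1 loss. The block therefore cannot fully separate array group from loss of p107 or p130. Array 9 of the Rb1 and p130 double knockout had the lowest median correlation with other arrays (0.939), followed by array 8 of that group and array 3 of the p130 KO (both 0.953).

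**Figure D2:**
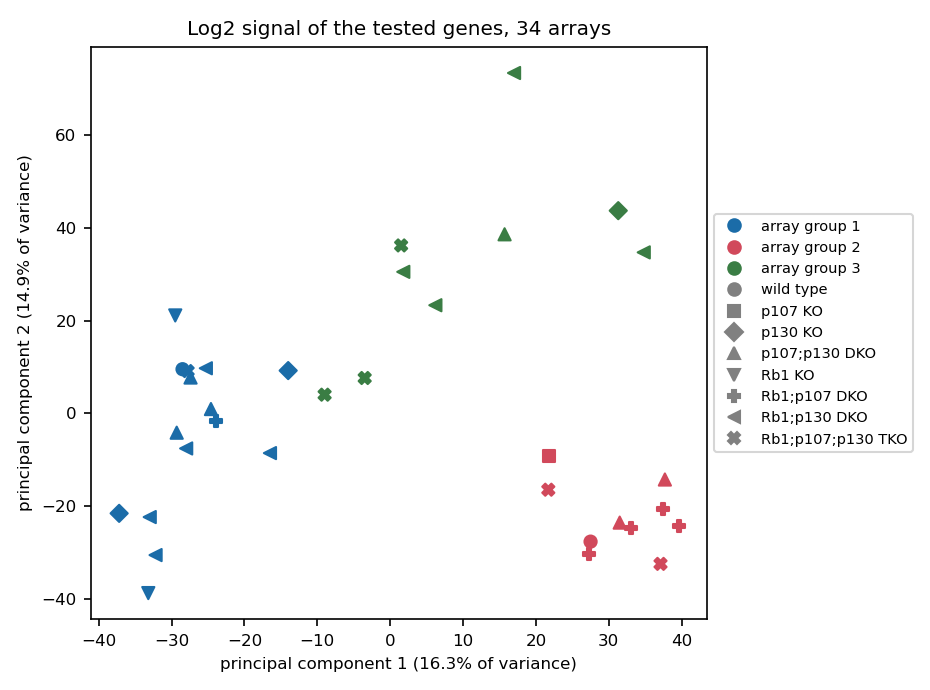
Position of each of the 34 arrays on the first (16.3% of variance) and second (14.9%) principal components of log2 signal over 12719 genes. Colour marks the array group and marker shape the genotype, and 89.0% of the variance of the first component lies between array groups.

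Loss of Rb1 changed a set of genes across genetic backgrounds, compared here between the 22 arrays without Rb1 and the 12 with it. Cdkn1a, which encodes an inhibitor of cyclin-dependent kinases induced by p53, rose 2.28-fold (log2 change 1.19 ± 0.12 SE, adjusted p = 7.15e-09) and was above the mean of the Rb1-carrying arrays on 22 of 22 arrays. Phf13, a chromatin reader, rose 2.05-fold (1.04 ± 0.07, adjusted p = 2.20e-13, 22 of 22), and the zinc-finger gene Zfp367 rose 2.14-fold (1.10 ± 0.11, 22 of 22). The immediate-early gene Fos rose by 1.15 ± 0.12, the pro-apoptotic p53 target Bbc3 by 1.05 ± 0.20 and Trp53inp1 by 0.92 ± 0.14, each on at least 21 of 22 arrays. Klf5 (1.14 ± 0.20), Otud1 (1.10 ± 0.14), Nudt4 (1.05 ± 0.11) and Hspa1a (1.05 ± 0.26) also rose. Apart from Rb1 itself (log2 change -2.43 ± 0.11), Tcp11l2 fell 2.57-fold (-1.36 ± 0.13, 22 of 22) and the interferon-induced gene Rsad2 2.30-fold (-1.20 ± 0.24, 21 of 22). Epor, the erythropoietin receptor gene that red cell precursors need, fell 1.78-fold (-0.83 ± 0.10, adjusted p = 1.51e-07, 22 of 22).

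Further genes that fell with Rb1 loss included Xpo7 (-0.68 ± 0.09), a nuclear exportin abundant in maturing red cells whose gene lies 2.42 Mb from Rb1, Ube2o (-0.68 ± 0.12), Mllt3 (-0.63 ± 0.08), Pld3 (-0.61 ± 0.12), Bsdc1 (-0.59 ± 0.10) and Ube2h (-0.59 ± 0.10). In all, 289 of 12719 genes were called, 223 higher and 66 lower, with 1439 at an unadjusted p under 0.05. With array group as a block 561 were called, 380 higher and 181 lower, and the 289 were called again with the same sign. 14 of the 289 changed at least 2-fold. Within the first and second array groups each of the 289 kept its sign, on arrays that also chose the calls. Within the third, with 7 arrays without Rb1 and 2 with it, 268 did. Leaving out any 1 array gave 241 to 337 calls.

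**Figure D3:**
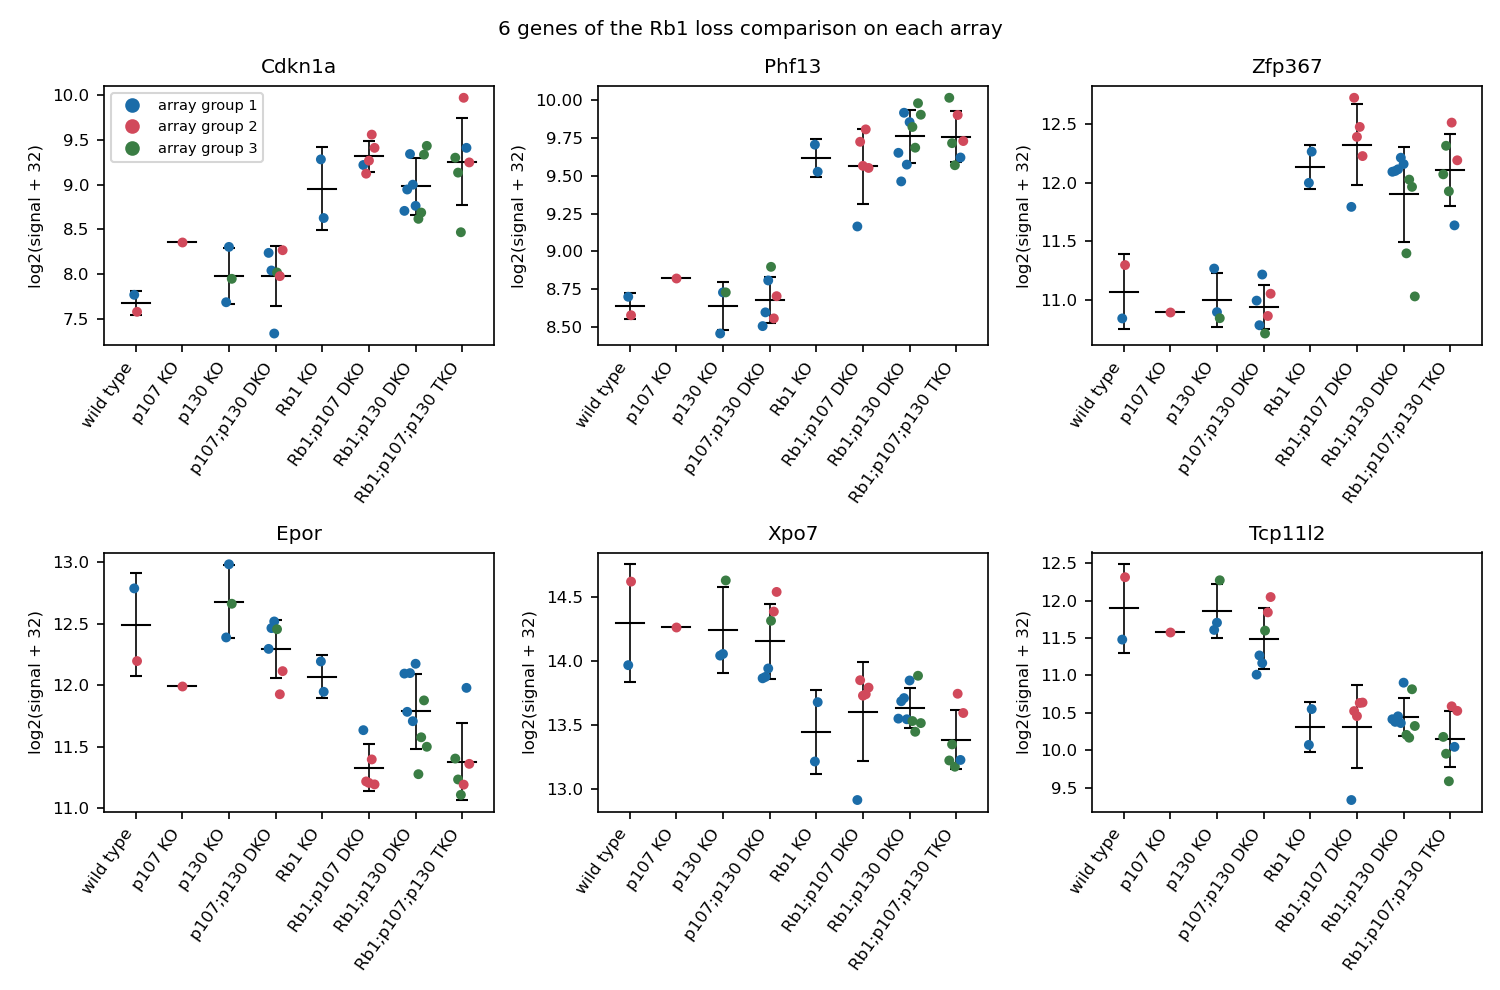
Log2(signal + 32) of 6 genes on each array, by genotype. Points are arrays coloured by array group, horizontal lines are group means and error bars are 1 SD; Cdkn1a, Phf13 and Zfp367 lie higher and Epor, Xpo7 and Tcp11l2 lower in the groups without Rb1.

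Some cell-cycle genes rose with Rb1 loss by small amounts. Among S-phase and E2F target genes, E2f1 rose by 0.46 ± 0.07, E2f8 by 0.54 ± 0.09, E2f7 by 0.42 ± 0.08 and the histone mRNA-binding gene Slbp by 0.26 ± 0.05. 6 of 38 members were called over all genes tested and 10 when adjusted over the list alone, each higher. The list's median log2 change was 0.09 (camera adjusted p = 1.59e-07, with the block 4.18e-08), and adjusted p = 0.250 with an estimated correlation. Within array groups the medians were 0.13, 0.15 and -0.08, so the direction did not hold in the third, where 2 arrays carry Rb1. Among G2/M genes, Prc1 rose by 0.29 ± 0.05, Cdk1 by 0.23 ± 0.04, Nusap1 by 0.42 ± 0.09 and Tpx2 by 0.28 ± 0.07. 8 of 29 were called over all genes tested and 12 adjusted over the list alone, each higher, with a median of 0.18 (adjusted p = 1.18e-12). For this list adjusted p = 0.0697 with an estimated correlation, and within array groups the medians were 0.19, 0.25 and 0.12. Of the pocket protein and cell-cycle regulator genes, the kinase inhibitors Cdkn2c (0.69 ± 0.08, adjusted p = 2.06e-07), Cdkn2d (0.52 ± 0.09) and Cdkn1b (0.45 ± 0.11) rose. That list had 4 higher and 1 lower over all genes tested, 5 and 1 adjusted over the list alone, a median of 0.005, a mean of -0.02 and an upward test (adjusted p = 0.235).

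Of 14 p53 target genes, 3 were called over all genes tested and 4 adjusted over the list alone, each higher. Cdkn1a, Bbc3 and Trp53inp1 were the 3. The list's median was 0.09 and its mean 0.28 (adjusted p = 1.34e-04), and within array groups the medians were 0.11, -0.002 and 0.32. It was the single list call, of 73 in 234 tests, that held with an estimated correlation (adjusted p = 0.0400). With the array group block 59 list tests were called, and 6 with block and estimated correlation together. Hypoxia-response genes had 2 of 20 higher over all genes tested and adjusted over the list alone, Kdm3a (0.51 ± 0.10) and Ankrd37 (0.59 ± 0.13), with a median of 0.09 (adjusted p = 0.0190, and 0.250 with an estimated correlation). Without arrays 8 and 9 of the Rb1 and p130 double knockout this list was not called. Histone genes had 0 of 6 called over all genes tested and 3 adjusted over the list alone, with a median of 0.18 (adjusted p = 0.00990, and 0.250 with an estimated correlation).

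Erythroid maturation genes did not move as a list. Epor, Xpo7, Bpgm (-0.52 ± 0.09) and Tmcc2 (-0.35 ± 0.09) fell, and 5 of 32 were called lower over all genes tested. Adjusted over the list alone, 4 were higher and 7 lower. The median was 0.04, the mean -0.06 and the test downward (adjusted p = 0.292), and the medians within array groups were 0.11, 0.12 and -0.29. Interferon-response genes had Rsad2 lower and no other call over all genes tested or over the list alone, with a median of 0.07, a mean of -0.04 and an upward test (adjusted p = 0.824). The lists that were not called and had 0 members past the threshold by limma over all genes tested were embryonic globin (median -0.09, adjusted p = 0.658), hepatocyte and hepatoblast (0.04, 0.149), macrophage (-0.05, 0.528), neutrophil and granule (0.004, 0.760), megakaryocyte and platelet (-0.04, 0.90), stem and progenitor cell (-0.09, 0.0821), endothelial (0.08, 0.101), stellate and mesenchymal (0.07, 0.646) and mitochondrial respiration genes (-0.05, 0.117). Lymphoid genes had a median of 0.05 and a downward test (0.959). By fry, which asks whether a list's members move one way on balance, stem and progenitor cell genes fell (adjusted p = 0.0440). Over all comparisons fry called 8 of the 234 list tests, of which only this one is given here.

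**Figure D4:**
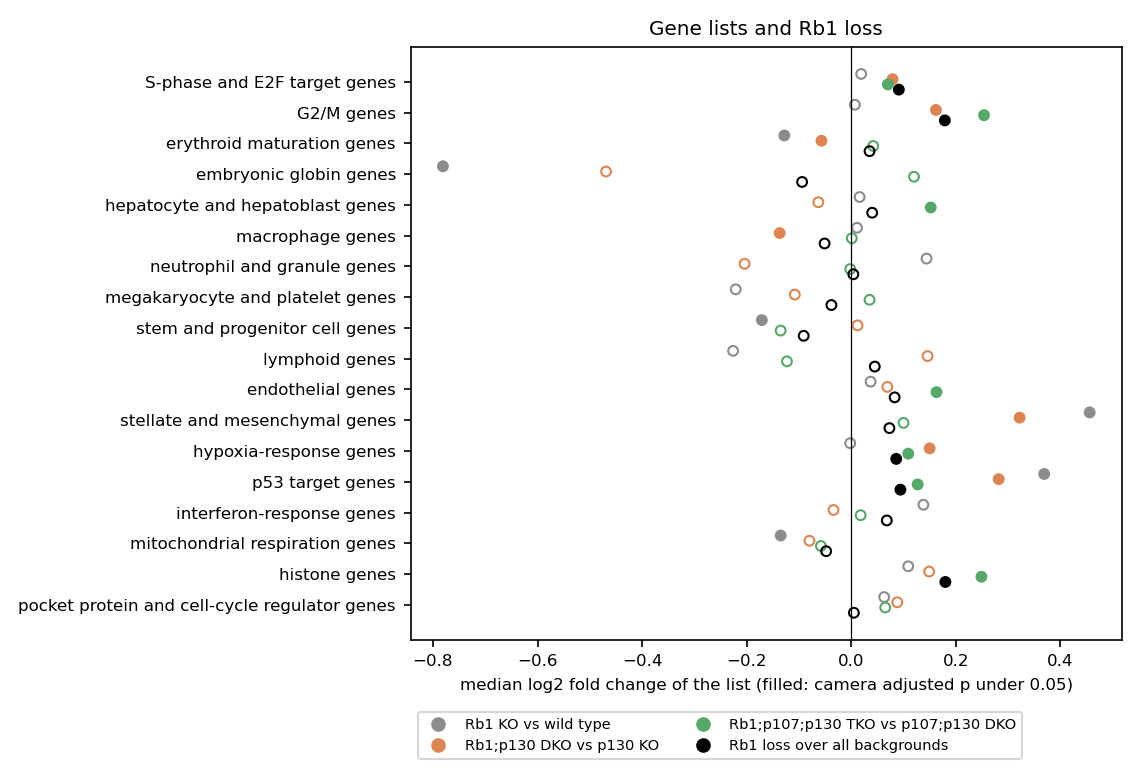
Median log2 change of each of the 18 gene lists (x axis) in the 4 comparisons of Rb1 loss, with a point per list and comparison, filled where the camera adjusted p is under 0.05. G2/M genes have a median of 0.18 over all backgrounds and 0.25 in the triple knockout against the p107 and p130 double knockout.

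Where p107 and p130 were both absent, the effect of Rb1 loss was read from the 6 triple knockout arrays against the 6 of the p107 and p130 double knockout. Otud1, a deubiquitinase gene, rose by 1.4 ± 0.21 (adjusted p = 2.49e-04), Cdkn1a by 1.28 ± 0.19 (2.42-fold), Fos by 1.19 ± 0.21, Zfp367 by 1.17 ± 0.18 and Phf13 by 1.08 ± 0.11 (adjusted p = 3.99e-07). Nudt4 (1.12 ± 0.18), Pdzk1ip1 (1.02 ± 0.17), Fhl1 (0.87 ± 0.15), Pcgf5 (0.85 ± 0.14) and Gm45914 (0.85 ± 0.13) also rose. Rb1 fell 5.50-fold (-2.46 ± 0.17), Tcp11l2 2.54-fold (-1.34 ± 0.21) and Xpo7 1.71-fold (-0.77 ± 0.15, adjusted p = 0.0104). Each of these lay beyond the double knockout mean on 6 of 6 arrays, which the naming rule requires. Mllt3 fell by 0.61 ± 0.13 and Ube2f by 0.37 ± 0.09 (adjusted p = 0.0495), but neither call was secure. Mllt3 lost its call without array 2, 3 or 4 of the double knockout or 4 of the triple knockout (adjusted p 0.0529 to 0.0697). Ube2f lost it without any of double knockout arrays 2 to 6 or triple knockout arrays 1 to 6 (0.0547 to 0.129).

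49 genes were called between these groups, 39 higher and 10 lower, with 768 at an unadjusted p under 0.05, and 110 with the array group block, 88 higher and 22 lower, which included 48 of the 49. The count fell to 28 without array 2 of the double knockout, 31 without array 3 of it and 30 without array 2 of the triple knockout. Within the 3 array groups 48, 49 and 48 of the 49 kept their sign, on arrays that also chose the calls. Xist marked 4 of the 6 triple knockout arrays and 1 of the 6 double knockout arrays. Sex was not fitted, so it is partly confounded with Rb1 loss here. G2/M genes had a median of 0.25 (adjusted p = 1.18e-12), with 0 of 29 called over all genes tested by limma and 4 adjusted over the list alone, and adjusted p = 0.0625 with an estimated correlation. S-phase and E2F target genes had a median of 0.07 (adjusted p = 8.85e-05) with 1 called over all genes tested, E2f8 (0.62 ± 0.15), and 6 adjusted over the list alone, and adjusted p = 0.347 with an estimated correlation. E2f8 lost its call without double knockout array 1, 2, 3 or 5 or triple knockout array 1, 2, 4 or 6 (adjusted p 0.0711 to 0.150). p53 target genes had a median of 0.13 (adjusted p = 4.68e-04), Cdkn1a as the 1 called over all genes tested and 3 adjusted over the list alone, and adjusted p = 0.0625 with an estimated correlation.

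Of the remaining lists in this comparison, hepatocyte and hepatoblast (median 0.15, adjusted p = 0.00173), histone (0.25, 0.00595), endothelial (0.16, 0.0236) and hypoxia-response genes (0.11, 0.0393) were called higher, with adjusted p between 0.250 and 0.672 with an estimated correlation. The endothelial and hypoxia-response calls were not kept with the array group block (adjusted p = 0.163 and 0.0629). Histone genes lost the call without triple knockout array 4 (0.101). The endothelial list lost it without double knockout array 1 or 2 or triple knockout array 2 or 6 (0.0688 to 0.143), and the hypoxia-response list without double knockout array 1, 2 or 3 or triple knockout array 4, 5 or 6 (0.0509 to 0.162). Erythroid maturation genes had Epor (-0.92 ± 0.16, adjusted p = 0.00111) and Xpo7 lower over all genes tested and 3 lower adjusted over the list alone, while the list had a median of 0.04, a mean of -0.07 and a downward test (adjusted p = 0.292). Cdkn2c rose by 0.68 ± 0.13 (adjusted p = 0.00786).

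Where p130 alone was absent, Rb1 loss was read from the 9 arrays of the Rb1 and p130 double knockout against the 3 of the p130 KO. Phf13 rose 2.18-fold (1.12 ± 0.13, adjusted p = 4.79e-06), and Fhl1 (0.91 ± 0.18), Pcgf5 (0.81 ± 0.16), Klf10 (0.77 ± 0.16), Phlpp2 (0.67 ± 0.13), Sap30 (0.63 ± 0.13) and Siah1a (0.61 ± 0.12) rose. Rb1 (-2.27 ± 0.20), Tcp11l2 (2.67-fold, adjusted p = 0.00511), Epor (-0.89 ± 0.18, adjusted p = 0.0224) and Prokr1 (-0.69 ± 0.15) fell. Each of these genes lay beyond the p130 KO mean on 9 of 9 arrays, which the naming rule requires. 15 genes were called, 9 higher and 6 lower, and 50 with the array group block, 37 higher and 13 lower. The count fell to 7 without p130 KO array 1, 7 without array 2 and 9 without array 3. Leaving out a p130 KO array ended the call of each named gene except Rb1 and Phf13, with adjusted p up to 0.362. Sap30 also lost it without arrays 7 or 8 of the double knockout, Siah1a without array 8, and Prokr1 without arrays 1, 3, 6, 8 or 9 (0.0513 to 0.0790).

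The lists called in this comparison were p53 target (median 0.28, adjusted p = 0.00426), hypoxia-response (0.15, 0.00293), G2/M (0.16, 1.17e-04), S-phase and E2F target (0.08, 0.0166) and stellate and mesenchymal genes (0.32, 0.0403), higher, and erythroid maturation (-0.06, 0.0110) and macrophage genes (-0.14, 0.0146), lower. Their adjusted p was 0.114 to 0.791 with an estimated correlation, and the mesenchymal call was not kept with the array group block (0.0761). Over all genes tested 1 hypoxia-response gene, Ankrd37 (1.14 ± 0.23), and 1 erythroid gene, Epor, were called. Adjusted over the list alone 4 p53 target genes and 2 hypoxia-response genes were higher and 3 erythroid genes lower. Ankrd37 lost its call without p130 KO array 2 or 3 (adjusted p = 0.103 and 0.551). Cdkn1a, at 1.00 ± 0.22, missed the threshold (adjusted p = 0.0574). These list calls rested on few arrays. Without p130 KO array 2 the S-phase and macrophage medians changed sign (-0.05 and 0.04), and G2/M (adjusted p = 0.146) and hypoxia-response genes (0.0647) lost their calls. Without p130 KO array 3 erythroid maturation (0.956), p53 target (0.0538) and mesenchymal genes (0.348) lost theirs. The mesenchymal call was also lost without p130 KO array 1 (0.765) and without double knockout array 1, 2, 4 or 9 (0.0543 to 0.297), the erythroid call without double knockout array 7 (0.0873), the S-phase call without array 8 (0.0847) and the macrophage call without array 9 (0.134).

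With p107 and p130 present, 2 Rb1 KO arrays were compared with 2 wild type arrays. Rb1 fell 4.75-fold (-2.25 ± 0.30, adjusted p = 1.59e-04, lower on 2 of 2 arrays). Phf13 (0.98, adjusted p = 0.136) was called when array group was a block (1.05, adjusted p = 0.0213) and is named outside the rule, chosen after its values were seen. Cdkn1a (1.28 ± 0.33, adjusted p = 0.698) and Bbc3 (1.68 ± 0.56) were not called. Rb1 was the single call by limma, with 440 genes at an unadjusted p under 0.05 where 636 would be expected by chance. The number called was 2 without wild type array 1, 0 without wild type array 2 (adjusted p for Rb1 0.0883), 4 without Rb1 KO array 1 and 2 without Rb1 KO array 2. Embryonic globin genes (median -0.78, adjusted p = 0.00749), erythroid maturation genes (-0.13, 0.0143), stem and progenitor cell genes (-0.17, 0.0326) and mitochondrial respiration genes (-0.14, 0.0361) were called lower as lists, and p53 target (0.37, 0.0262) and mesenchymal genes (0.46, 0.0229) higher, with adjusted p of 0.208 to 0.791 with an estimated correlation. Adjusted over the list alone 2 p53 target genes were higher and 1 embryonic globin gene lower, and 0 over all genes tested. Each of these 6 list calls was lost without 1 or more of the 4 arrays (adjusted p 0.0576 to 0.728), and without wild type array 2 the erythroid median was 0.17. None was kept with the array group block (adjusted p 0.0546 to 0.519), where S-phase (median 0.11, adjusted p = 0.00262), G2/M (0.12, 0.0212), endothelial (0.18, 0.0212) and histone genes (0.31, 0.00906) were called higher. These used the preset correlation. Over all comparisons 59 list tests were called with the block, and 6 with block and estimated correlation together.

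The genes called for Rb1 loss moved alike in comparisons that share no array. Of the 48 genes other than Rb1 called between the triple knockout and the p107 and p130 double knockout, 48 had the same sign in the Rb1 and p130 double knockout against p130 KO and 47 in Rb1 KO against wild type. Their median log2 changes were 0.73, 0.62 and 0.57. Across all genes the correlations of the effects with these 2 comparisons were 0.273 and 0.135, across genes that are not independent replicates. Of the 14 genes other than Rb1 called in the Rb1 and p130 double knockout against p130 KO, 14 had the same sign in each of the other comparisons and 11 were also called in the triple knockout.

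Whether the effect of Rb1 loss depends on p107 and p130 was tested as the difference between its effect with both absent and with both present. By limma 0 genes were called, with 266 at an unadjusted p under 0.05, and 0 with the array group block, with 277. For Rb1 the difference was -0.21 ± 0.35. Among the lists, the difference was 0.12 for S-phase and E2F target genes (adjusted p = 0.0145), 0.28 for G2/M genes (1.37e-06) and 1.12 for embryonic globin genes (4.28e-04), with adjusted p of 0.672, 0.250 and 0.189 with an estimated correlation. 2 of the 3 embryonic globin genes passed adjusted over the list alone and 0 over all genes tested. With the array group block the values were -0.02 (adjusted p = 0.700), 0.12 (0.0360) and 0.75 (0.0244), so the S-phase difference was not kept. Without wild type array 2 none of the 3 was called (adjusted p = 0.400, 0.0620 and 0.102), and the S-phase call was also lost without Rb1 KO array 2 or triple knockout array 4 (0.130 and 0.123).

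**Figure D5:**
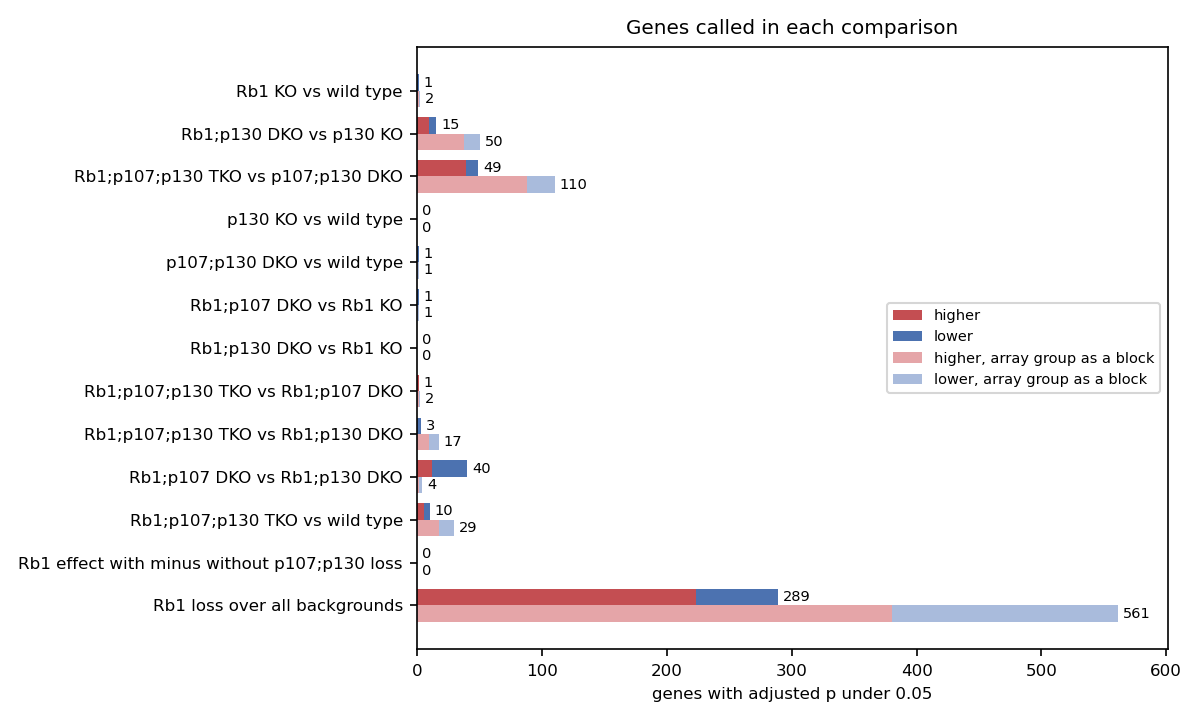
Number of genes called higher and lower (adjusted p under 0.05) in each comparison, without and with array group as a block. The count rises from 289 to 561 for Rb1 loss over all backgrounds and falls from 40 to 4 between the Rb1 and p107 and the Rb1 and p130 double knockouts.

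Few genes were called for loss of p130 alone, or of p107 and p130 together, with Rb1 present. In simulated data with the same numbers of arrays but no array groups, 10% of 1.5-fold and 35% of 2-fold changes were recovered in p130 KO against wild type. The shares were 13% and 58% in the double knockout against wild type. In p130 KO against wild type (3 against 2 arrays) Rbl2 was lower by 0.76 ± 0.29 on 3 of 3 arrays, which missed the threshold (adjusted p = 1.00). limma called 0 genes, with 261 at an unadjusted p under 0.05, and 1 without wild type array 2. In the p107 and p130 double knockout against wild type (6 against 2) Rbl1 fell from a mean signal of 1407 to 73.3 (-3.80 ± 0.28, adjusted p = 5.37e-11, 6 of 6) and was the single call, with 250 genes at an unadjusted p under 0.05. Since the lower signal lies near background, the size of this change depends on the 32 added before taking logs, here and below. Rbl2 had a log2 change of -0.85 ± 0.26, lower on 6 of 6 arrays, without passing (adjusted p = 1.00).

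As lists, macrophage (median 0.32, adjusted p = 0.00188), neutrophil (0.43, 0.00493) and interferon-response genes (0.14, 0.0133) were called higher in p130 KO than in wild type, and G2/M (-0.09, 0.0236), mesenchymal (-0.22, 0.0403) and hypoxia-response genes (-0.11, 0.0403) lower, with 0 members called over all genes tested or adjusted over the list alone. Their adjusted p was 0.250 to 0.791 with an estimated correlation, and the G2/M and hypoxia-response calls were not kept with the block (0.889 and 0.305). The 3 lists called higher rested on p130 KO array 2, whose mean log2 signal was 10.41 for macrophage genes against 9.71 and 9.81 on the other p130 KO arrays and 9.76 and 9.66 in wild type. Without it their medians were -0.02, 0.18 and -0.002 (adjusted p = 0.894, 0.564 and 0.623). They also lost their calls without wild type array 1 (0.0934 to 0.174), and the interferon-response list without p130 KO array 1 (0.0564). Of the lists called lower, G2/M genes had a median of 0.05 without wild type array 2 and lost the call without it or p130 KO array 1 or 2 (0.0586 to 0.642), mesenchymal genes lost it without either wild type array or p130 KO array 1 or 3 (0.0879 to 0.688), and hypoxia-response genes without either wild type array or p130 KO array 2 (0.0626 to 0.421). In the double knockout erythroid maturation (-0.15, 3.75e-05) and hepatocyte and hepatoblast genes (-0.21, 5.37e-05) were called lower, interferon-response (0.32, 0.00151) and macrophage genes (0.21, 0.0231) higher, and cell-cycle regulators lower (-0.09, 8.70e-04), a list that holds Rbl1 itself. Their adjusted p was 0.0781 to 0.756 with an estimated correlation. The erythroid and hepatocyte calls rested on wild type array 2, where the means were 13.73 and 12.56 against 13.29 and 12.17 on wild type array 1. Without it the medians were 0.08 and 0.04 (adjusted p = 0.184 and 0.664). The interferon-response and regulator calls were lost without wild type array 1 (both 0.0973), the regulators then at a median of 0.08, and the macrophage call without either wild type array or double knockout array 3 or 4 (0.0617 to 0.276).

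With Rb1 absent, further loss of p107 was read from the 5 Rb1 and p107 double knockout arrays against the 2 Rb1 KO arrays. Rbl1 fell from a mean signal of 1382 to 69.5 (-3.80 ± 0.29, adjusted p = 1.02e-10, 5 of 5) and was the single call, with 1505 genes at an unadjusted p under 0.05 and 414 with the array group block. 3 genes were called without Rb1 KO array 1, 2 without Rb1 KO array 2 and 2 without double knockout array 5. S-phase (median 0.25, adjusted p = 8.85e-05) and G2/M genes (0.24, 1.74e-04) were called higher, but not with the block (0.519 and 0.735). They and the 7 further lists called in this comparison had adjusted p of 0.250 to 0.791 with an estimated correlation. Erythroid maturation genes changed direction, from a median of 0.18 (0.0262) to -0.13 with the block (8.46e-04). Embryonic globin (0.61, 0.0110), megakaryocyte (0.32, 0.0407), stem and progenitor cell (0.26, 0.0403), hypoxia-response (0.22, 0.0272) and mitochondrial genes (0.15, 0.0404) were called higher and cell-cycle regulators lower (-0.09, 0.0447). With the block the stem and progenitor cell call was kept narrowly (0.0497), and the globin (0.133), megakaryocyte (0.741), hypoxia-response (0.177), mitochondrial (0.249) and regulator calls (0.310, at a median of 0.02) were not. Adjusted over the list alone 3 embryonic globin genes and 1 hypoxia-response gene were higher and 2 erythroid genes lower, and over all genes tested Rbl1 alone was called. Without Rb1 KO array 1 the erythroid, stem and progenitor cell, hypoxia-response and regulator calls were lost (0.198 to 0.518), and without Rb1 KO array 2 the globin, megakaryocyte and mitochondrial calls (0.117 to 0.276). Each of these except the globin call was also lost without 1 or more of the double knockout arrays (0.0540 to 0.174).

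Further loss of p130 with Rb1 absent, in 9 Rb1 and p130 double knockout arrays against the same 2, left 0 genes called by limma, with 292 at an unadjusted p under 0.05. 2 were called without Rb1 KO array 1 and 1 without Rb1 KO array 2. Rbl2 was lower by 0.78 ± 0.25 on 9 of 9 arrays without passing (adjusted p = 1.00). Stellate and mesenchymal genes were called lower (median -0.34, adjusted p = 5.17e-04, with the block 7.38e-05), and adjusted p = 0.496 with an estimated correlation. This call rested on Rb1 KO array 1, whose mean was 9.86 against 9.28 on Rb1 KO array 2. Without it the median was -0.105 (adjusted p = 0.569).

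In the triple knockout against the Rb1 and p107 double knockout (6 against 5 arrays), which adds loss of p130, Arl2bp rose 2.66-fold, from a mean signal of 507.9 to 1324 (1.41 ± 0.18, adjusted p = 5.18e-05, 6 of 6), and was the single call, with 955 genes at an unadjusted p under 0.05. With the array group block Rbl2 was called too (-1.03, adjusted p = 0.0325). S-phase genes (median -0.11, adjusted p = 5.37e-05, with the block -0.06 and 0.00723) and erythroid maturation genes (-0.22, 2.05e-08, with the block -0.04 and 0.150) were called lower, both with adjusted p = 0.347 with an estimated correlation.

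In the triple knockout against the Rb1 and p130 double knockout (6 against 9), which adds loss of p107, Rbl1 fell from a mean signal of 2078 to 87.6 (-4.12 ± 0.18, adjusted p = 1.01e-17). Ccne1, which encodes cyclin E1, fell from a mean signal of 3693 to 2678 (-0.46 ± 0.09, adjusted p = 0.0368, 6 of 6, with the block -0.44 and 0.0446). Its call was lost without array 1, 4, 5 or 8 of the double knockout or 1, 2, 3 or 4 of the triple knockout (adjusted p 0.0637 to 0.176). Serinc3, the remaining call, fell by 1.70 ± 0.27 (adjusted p = 0.00304) and lies outside the naming rule, so it was chosen after its values were seen. 3 genes were called, with 0 higher and 692 at an unadjusted p under 0.05 by limma, 5 without array 7 of the double knockout and 8 without array 9 of it, and 17 with the array group block, 9 higher and 8 lower. Embryonic globin (median 0.49, adjusted p = 0.00173), G2/M (0.13, 1.17e-05), mesenchymal (0.30, 0.00143), histone (0.28, 0.0136), megakaryocyte (0.16, 0.0404) and hypoxia-response genes (0.08, 0.0361) were called higher and erythroid maturation (-0.06, 0.0388) and neutrophil genes (-0.21, 0.0129) lower, with adjusted p of 0.250 to 0.812 with an estimated correlation. Adjusted over the list alone 2 globin genes and 1 mesenchymal gene were higher, and 0 over all genes tested. With the block the erythroid median was -0.18 (4.89e-12), and the globin (0.0806), G2/M (0.186), histone (0.344), megakaryocyte (0.799) and hypoxia-response calls (0.335) were not kept. The histone call was lost without triple knockout array 4 (0.196), and the erythroid, neutrophil, megakaryocyte and hypoxia-response calls without any of 8, 5, 9 and 6 of the 15 arrays (0.0504 to 0.787).

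Between the double knockouts that lack Rb1, p107 loss was set against p130 loss (5 Rb1 and p107 against 9 Rb1 and p130 arrays). Rbl1 was lower where p107 was lost, at a mean signal of 69.5 against 2078 (-4.34 ± 0.19, adjusted p = 1.17e-17, with the block -4.23), and Arl2bp 3.46-fold lower (-1.79 ± 0.16, 1.21e-08, with the block -1.84 and 1.97e-06). Serinc3, outside the naming rule and chosen after its values were seen, had a log2 change of -1.90 (7.48e-04, with the block -1.97 and 0.00737). Rbl2 was higher by 0.71 ± 0.18, which passed with the block alone (0.0595 and 0.0163). Sdc4 (2.53 ± 0.49), Zeb2 (0.98 ± 0.20), Ipo4 (0.90 ± 0.18), Pdgfrb (0.87 ± 0.17), Srebf1 (0.75 ± 0.15), Armc5 (0.74 ± 0.17), Stk4 (0.65 ± 0.11), Hax1 (0.60 ± 0.12) and Eftud2 (0.54 ± 0.11) were called higher. Wdr91 (-0.93 ± 0.15), Rps6kb2 (-0.86 ± 0.17), Samd11 (-0.85 ± 0.18), Ankle1 (-0.67 ± 0.15), Mta2 (-0.62 ± 0.15), Spint2 (-0.58 ± 0.13), Kdm4a (-0.50 ± 0.11) and Ep400 (-0.50 ± 0.12) were called lower, each on 5 of 5 arrays, which the naming rule requires. None of these 17 was called with the array group block in this comparison. In the additive fit for p107 loss with the block, Sdc4 (1.43, adjusted p = 0.00369), Stk4 (0.31, 0.00763), Pdgfrb (0.56, 0.0129) and Samd11 (-0.50, 0.0320) were called. Zeb2, Ipo4, Armc5, Eftud2, Wdr91, Rps6kb2 and Spint2 were called in that fit without the block only. Sdc4 and Stk4 lie within 20 Mb of Rbl1.

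40 genes were called, 12 higher and 28 lower, and 4 with the block, 3 of them shared. The 40 kept their signs with the block, while their median size fell from 0.80 to 0.38 and their median SE from 0.162 to 0.154. In the first array group, which holds 1 and 5 of these arrays, 39 of the 40 kept their sign, though these arrays also chose the calls. No other array group holds both genotypes. The count also rested on single arrays. It was 811 without array 1 of the Rb1 and p107 double knockout, 7 without 2, 6 without 3, 9 without 4 and 11 without 5. Without arrays of the Rb1 and p130 double knockout it was 25 (array 1), 20 (array 2), 20 (array 3), 23 (array 6) and 101 (array 8). Of the named genes, Rbl1, Arl2bp, Stk4 and Wdr91 stayed called without any 1 array. The others lost their calls without 1 or more of arrays 2 to 5 of the first group, or 1, 2, 3, 5, 6, 7 or 9 of the second, with adjusted p up to 0.153. As lists, S-phase (median 0.15, adjusted p = 2.95e-04), G2/M (0.15, 8.78e-04), histone (0.33, 0.00704), embryonic globin (0.32, 0.0116) and hypoxia-response genes (0.14, 0.0393) were called higher without keeping the call with the block (0.0567 to 0.939). These lists and erythroid maturation genes had adjusted p of 0.250 to 0.770 with an estimated correlation. Erythroid maturation genes went from 0.18 (0.00384) to -0.13 with the block (1.38e-06), with 1 member called over all genes tested, Ppox (-0.52 ± 0.12), and 1 higher and 3 lower adjusted over the list alone. The hypoxia-response call was lost without array 1 or 5 of the first group or 5 of the second (0.0614 to 0.0896).

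Loss of the whole family was read from the 6 triple knockout arrays against 2 wild type arrays. Besides Rbl1 (-3.61 ± 0.28) and Rb1 (-2.67 ± 0.24), Tcp11l2 fell 3.36-fold (-1.75 ± 0.30, adjusted p = 0.00323) and Epor 2.16-fold (-1.11 ± 0.22, adjusted p = 0.0204). Cdkn1a rose (1.58 ± 0.27, adjusted p = 0.00323), Phf13 2.17-fold (1.12 ± 0.16), Fhl1 2.04-fold (1.03 ± 0.21) and Sap30 1.83-fold (0.87 ± 0.16), each on 6 of 6 arrays, which the naming rule requires. 10 genes were called, 5 higher and 5 lower, 29 with the array group block, 17 higher and 12 lower, and 4 without wild type array 2. Without wild type array 2 the adjusted p was 0.220 for Cdkn1a, 0.479 for Tcp11l2, 0.444 for Sap30, 0.196 for Fhl1, 0.0544 for Phf13 and 0.0531 for Epor. Without wild type array 1 it was 0.0616 for Cdkn1a and Sap30, 0.463 for Fhl1 and 0.533 for Epor. Fhl1 also lost its call without triple knockout array 2, 4 or 6 (0.0660 to 0.0963) and Epor without 2, 3 or 4 (0.0536 to 0.0586).

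As lists, G2/M (median 0.20, adjusted p = 4.78e-05), p53 target (0.23, 0.0403), hypoxia-response (0.20, 0.0403), histone (0.43, 0.0336), interferon-response (0.39, 0.0236) and mesenchymal genes (0.24, 0.0449) were called higher in the triple knockout than in wild type, and erythroid maturation genes lower (-0.08, 1.17e-05). These lists and cell-cycle regulators had adjusted p of 0.250 to 0.791 with an estimated correlation. Cell-cycle regulators, which include the deleted genes, had a median of 0.05, a mean of -0.24 and a downward test (0.0431). Over all genes tested Cdkn1a and Epor were called in their lists, and adjusted over the list alone 1 p53 target gene was higher, 2 erythroid genes were lower, and interferon-response genes had 2 higher and 1 lower. The mesenchymal and regulator calls were not kept with the block (0.102 and 0.181). Each rested on a wild type array. Without array 1 the G2/M, mesenchymal, hypoxia-response, interferon-response, histone and regulator calls were lost (0.157 to 0.650). Without array 2 the erythroid and p53 target medians changed sign (0.14 and -0.05, adjusted p = 0.728 and 0.585), and the mesenchymal and interferon-response calls were lost (0.0599 and 0.0832). The calls other than G2/M and erythroid were also lost without 1 or more triple knockout arrays (0.0626 to 0.197).

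The single p107 KO array differed at least 2-fold from both wild type arrays, in the same direction, for 293 genes, 187 higher and 106 lower. The 2 wild type arrays differed at least 2-fold from each other for 776 genes. The median log2 difference of the p107 KO array from the wild type mean was 0.99 for stellate and mesenchymal genes, 0.53 for interferon-response genes, 0.36 for hypoxia-response genes and -0.34 for hepatocyte and hepatoblast genes. Against wild type array 2, which lies in the same array group, it was 0.88, 0.40, 0.31 and -0.59. These 4 lists were chosen after their values were seen, as those beyond nearly every one of 10000 random gene lists of the same size. That comparison does not test the genotype, which has 1 array.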

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

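Of the tests in this part, those of array groups for the calls between the double knockouts that lack Rb1 were chosen only after the result was seen. The counts over other splits of the arrays were planned, but the splits were drawn again after first counts had been seen.

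In groups of 4 to 10 arrays, single arrays that lay far outside the spread of the others in their group were sought for list means, named genes and array measures. Chance marks about 1 in 20 groups, which is 14 of the 280 groups tested, and 26 were found. Array 1 of the Rb1 and p107 double knockout accounted for 10 of the 26 and is its group's single array in the first array group. Its mean log2 signal was the lowest of its group for erythroid maturation genes (13.18, the others 13.55 to 13.60), endothelial genes (8.60) and histone genes (11.16). It was the lowest for Tcp11l2 (9.34), Trp53inp1 (8.76), Ube2h (10.94), Ube2o (10.41) and Xpo7 (12.91), and the highest for Mllt3 (11.02) and Zeb2 (10.02). In the same group Ccne1 was lowest on array 2 (11.28) and Spint2 on array 5 (8.87).

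The remaining arrays were spread over 3 genotypes. In the Rb1 and p130 double knockout, array 8 had the highest mean of S-phase and E2F target genes (12.26, the others 12.04 to 12.14), array 9 the highest mean of endothelial genes (9.13), array 6 the lowest Armc5 (8.43) and Klf10 (10.20), and array 7 the highest Mllt3 (11.73). In the triple knockout, array 5 had the highest Bbc3 (10.31) and Epor (11.98), array 4 the lowest Kdm4a (8.72) and array 1 the lowest Zeb2 (8.58). In the p107 and p130 double knockout, array 3 had the lowest mean of mitochondrial respiration genes (12.29) and the lowest Cdkn1a (7.34), array 4 the highest Fhl1 (9.91), and array 1 the lowest Pld3 (10.01) and the highest Siah1a (10.64).

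The effect of Rb1 loss was called as differing between backgrounds, by the interaction term, for 3 lists. Their median log2 difference, with minus without joint p107 and p130 loss, was 0.12 for S-phase and E2F target genes, 0.28 for G2/M genes and 1.12 for embryonic globin genes. None of the 3 was called with an estimated correlation, and with the array group block the values were -0.02 (adjusted p = 0.700), 0.12 (0.0360) and 0.75 (0.0244). Without wild type array 2 none of the 3 was called (0.400, 0.0620 and 0.102). The side with p107 and p130 present rests on 2 arrays per group.

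The 40 genes called between the Rb1 and p107 and the Rb1 and p130 double knockouts may partly reflect array groups, in which the genotypes are unevenly placed. Of the 40, 3 were called with the same sign when array group was a block, Rbl1, Arl2bp and Serinc3. Rbl1 is the deleted gene, Serinc3 lies 6.42 Mb from it and Arl2bp 3.54 Mb from Rbl2. DNA of another strain carried beside the mutated alleles, taken up below, thus stays open for Serinc3 and Arl2bp. The median size of the 40 fell from 0.80 to 0.38 while their SE barely moved (0.162 to 0.154), so the other calls ended because their changes shrank. The 40 kept their signs, so a smaller difference between the genotypes stays open, and the first array group alone (1 against 5 arrays) is too small to decide it. Of 100 splits of these 14 arrays, 2 called as many genes, the real one included. The highest other split called 582 genes against 40 in the real one. It lies 76.7% between array groups, so it points to a structure of the samples that follows them. The real split lies 74.1% between array groups, against a median of 11.9%, and the splits did not hold array group fixed. That few splits called as many may therefore only reflect array groups.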

How the results depend on the processing

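The tests with array group as a block and without arrays 8 and 9 of the Rb1 and p130 double knockout were chosen after the results were seen, and the other alternatives were planned. None of the 100 results of genes named as called changed direction under an alternative. Named values of Rbl1 and Rbl2 that were not called were refitted with the array group block alone. There Rbl2 changed sign in Rb1 KO against wild type (0.10 to -0.14), the Rb1 and p107 double knockout against Rb1 KO (-0.07 to 0.32), the triple knockout against the Rb1 and p130 double knockout (-0.13 to 0.04) and the interaction (-0.06 to 0.21), and Rbl1 in Rb1 KO against wild type (-0.03 to 0.008), each within 2 SE of 0. With pseudocount 1, each of 100 gene results kept its side of the threshold, and 95 with pseudocount 100. No scaling alternative moved the median of all genes by 0.1 or more. Calls for lists depended most on the correlation between genes. With an estimated correlation 1 of 73 was kept. A list is counted as reversed when its test changed direction, which need not change the sign of its median. With quantile normalization 52 were kept and 2 reversed, both in the Rb1 and p107 double knockout against Rb1 KO, to medians of -0.034 for erythroid maturation and -0.051 for mitochondrial respiration genes. With array group as a block 39 were kept and 6 reversed. Their medians became 0.081 for erythroid maturation genes in Rb1 KO and -0.011 for G2/M genes in p130 KO, each against wild type, and -0.133 for erythroid maturation genes in the Rb1 and p107 double knockout against Rb1 KO. Between the Rb1 and p107 and the Rb1 and p130 double knockouts they became -0.040 for G2/M and -0.132 for erythroid maturation genes, and for S-phase and E2F target genes the interaction became -0.019. 4 further medians changed sign while the test kept its direction, to -0.089 for stem and progenitor cell genes (mean of all probe sets), 0.002 for macrophage genes (array weights), and 0.022 for regulators and -0.016 for histone genes (block). The cause was not tested for any of these or later changes unless stated.

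The count for Rb1 loss over all backgrounds stayed within 1.5 times of 289 under each alternative except array weights (508), array group as a block (561) and an added 2-fold threshold (14), which by construction keeps fewer. That threshold left 16 genes in the triple knockout against the p107 and p130 double knockout (49 without it), 6 in the Rb1 and p130 double knockout against p130 KO (15) and 7 between the Rb1 and p107 and the Rb1 and p130 double knockouts (40). With array weights these gave 145, 29 and 2130, the triple knockout 28 against the Rb1 and p107 and 8 against the Rb1 and p130 double knockout. With array group as a block they gave 110, 50 and 4, Rb1 KO against wild type 2, the triple knockout 29 against wild type, 2 against the Rb1 and p107 and 17 against the Rb1 and p130 double knockout.

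With only the arrays of the groups compared, and so fewer degrees of freedom, the counts were 0 for Rb1 KO against wild type, 5 for the Rb1 and p130 double knockout against p130 KO, 2 for the p107 and p130 double knockout against wild type, 3 for the Rb1 and p107 double knockout against Rb1 KO, 0 and 1 for the triple knockout against the Rb1 and p107 and the Rb1 and p130 double knockouts, 2 for it against wild type, and 225 between the Rb1 and p107 and the Rb1 and p130 double knockouts. This last count was also 120 with a signal of 200 or more on at least 6 arrays, 20 with the mean of all probe sets, 22 without the trend and 273 without arrays 8 and 9. No filter on low signal gave 2 for the Rb1 and p107 double knockout against Rb1 KO, as did the mean of all probe sets, which gave 0 for Rb1 KO against wild type. Quantile normalization gave 26 for the Rb1 and p130 double knockout against p130 KO.

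Replicate number is not stated to pair the samples. After group means were removed, arrays with the same number had a median correlation of 0.07 (31 of 67 pairs above 0.1) and arrays with different numbers -0.01 (84 of 380), against 0.13 within and -0.05 between array groups. With replicate number as a block the counts were 2 for Rb1 KO against wild type, 80 for the triple knockout against the p107 and p130 double knockout and 785 between the Rb1 and p107 and the Rb1 and p130 double knockouts. In that block the median of S-phase and E2F target genes in the Rb1 and p130 double knockout against p130 KO reversed to -0.021.

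Leaving out 1 array at a time gave 0 to 4 calls for Rb1 KO against wild type, 0 to 1 for p130 KO against wild type, 4 to 12 for the triple knockout against wild type, 7 to 17 for the Rb1 and p130 double knockout against p130 KO, 28 to 52 for the triple knockout against the p107 and p130 double knockout, 1 to 3 for the Rb1 and p107 double knockout against Rb1 KO, 0 to 2 for the Rb1 and p130 double knockout against Rb1 KO, 2 to 8 for the triple knockout against the Rb1 and p130 double knockout, and 6 to 811 between the Rb1 and p107 and the Rb1 and p130 double knockouts. Where a group kept 1 array, it was assumed to vary like the other groups. For Rb1 loss over all backgrounds the range was 241 to 337. In the Rb1 and p130 double knockout against p130 KO the S-phase median ran from -0.047 to 0.159 and the macrophage median from -0.341 to 0.04, both reversed without p130 KO array 2. Without wild type array 2 further medians reversed. The erythroid maturation median ran from -0.345 to 0.174 in Rb1 KO, from -0.432 to 0.08 in the p107 and p130 double knockout and from -0.351 to 0.137 in the triple knockout, each against wild type, the G2/M median from -0.25 to 0.05 in p130 KO and the hepatocyte and hepatoblast median from -0.441 to 0.042 in the p107 and p130 double knockout. Of the list results with 1 array left out, 701 kept their call, 136 lost it and 7 reversed in the direction of the test. In 8 more the median changed sign while the test kept its direction. Against wild type these were regulators in the p107 and p130 double knockout without wild type array 1 (0.084), p53 target genes in Rb1 KO (-0.008) and in the triple knockout (-0.051) and regulators in the latter (-0.133) without wild type array 2, and macrophage (-0.018) and interferon-response genes (-0.002) in p130 KO without array 2 of it. The others, for erythroid maturation genes, reached 0.009 and 0.01. Of the gene results with 1 array left out, 1780 kept their side of the threshold and 186 did not. Genes near the background of about 100 have little room to fall.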

Other observations

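Of the tests in this part, those of genes near Rbl1 and Rbl2, of a local effect, of array groups as the source of the concentration near Rbl1, and each of the tests of the Rb1 loss gene set were chosen after the result was seen. The test near Rb1 and that of array groups for the genes near Rbl1 were set before their results were seen. The splits were planned, but were drawn again after first counts had been seen, when the terms for p107 and p130 loss and the shares between array groups were added.

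Loss of p107 was also read from the additive fit. Ccne1, which was called as well between the triple knockout and the Rb1 and p130 double knockout, fell by 0.39 (adjusted p = 9.03e-05, with the array group block 0.00119). Pzp fell by 0.71 (0.00350, with the block 0.0137), while the cell-cycle inhibitor Cdkn1c rose by 0.61 (0.00812, with the block 0.00369) and the mitotic gene Cep55 by 0.37 (0.0477, with the block 0.0154). Melk (0.46), F9 (-0.67), F13b (-0.86) and Apof (-0.71) were called without the block but not with it (adjusted p 0.0512 to 0.149). These genes were chosen after their values were seen. A change in the mix of cells of the unsorted livers was not tested as a source of the p107 loss calls. 148 genes were called, 53 higher and 95 lower, and 85 with the block. The count depended on single arrays. It was 73 without wild type array 1 and 264 without wild type array 2, 94 and 93 without arrays 5 and 6 of the p107 and p130 double knockout, 92 and 74 without Rb1 KO arrays 1 and 2, and 98 without array 5 of the Rb1 and p107 double knockout. It was 95, 94 and 336 without arrays 1, 5 and 9 of the Rb1 and p130 double knockout, and 92, 75 and 87 without triple knockout arrays 2, 4 and 6. Loss of p130 called 2 genes, Rbl2 (-0.85) and Arl2bp (1.24 ± 0.15, adjusted p = 5.48e-06).

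Other splits of the same arrays, 100 per comparison with the real one included, ranked the number of calls. Fewer than 5 called as many for Rb1 loss over all backgrounds (2 splits, 289 real, 378 in the highest other) and for p107 loss (2 splits, 148 and 517). The same held for the triple knockout against the p107 and p130 double knockout (1 split, 49 and 38). Such counts were thus seldom reached by other splits. The splits ignored array group, and for Rb1 loss and p107 loss another split called more genes, so chance is not fully excluded. At least 5 splits called as many for p130 loss (5 splits, 2 and 1139) and the Rb1 and p130 double knockout against p130 KO (7 splits, 15 and 614). So did 5 splits for the triple knockout against the Rb1 and p130 double knockout (3 and 208). Chance is not excluded for these counts, but a count cannot judge single genes. The calls include deleted genes, such as Rbl1 in the last comparison (limma adjusted p = 1.01e-17). In the Rb1 and p130 double knockout against p130 KO, 14 of the 14 calls other than Rb1 kept their sign in comparisons that share no array. That argues against chance for those genes. For the triple knockout against the Rb1 and p107 double knockout fewer than 5 splits called as many in this draw alone (4 splits, 1 and 1575). An earlier draw fell on the other side of 5 splits for this comparison and for the triple knockout against the Rb1 and p130 double knockout. Neither result is therefore secure. Some splits that called several times the real count follow array groups, and others do not. The one with 1575 calls follows array group completely (100% between array groups), and 4 of those as large for the Rb1 and p130 double knockout against p130 KO lie 46.7% between array groups. The 378 split lies 14.6% between them and the 1139 split for p130 loss 11.7%. A split with 163 calls for the Rb1 and p130 double knockout against p130 KO lies 8.6% between them. What sets such splits apart was not tested. The real split for p107 loss lies 23.8% between array groups, against a median of 2.9% for all splits, which did not hold array group fixed, so the small number of splits as large may in part reflect array groups. With array group as a block the counts for these comparisons were 561, 85, 110, 50, 17 and 2 for Rb1 loss, p107 loss, the triple knockout against the p107 and p130 double knockout, the Rb1 and p130 double knockout against p130 KO, and the triple knockout against the Rb1 and p130 and the Rb1 and p107 double knockouts.

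The genes called for Rb1 loss over all backgrounds were weighed against 3 technical or compositional explanations. Array groups were argued against, since 289 of 289 calls stayed with the same sign under the block, and so were arrays 8 and 9 of the Rb1 and p130 double knockout, since 274 stayed without them. A lower share of erythroid cells would lower erythroid genes as a whole, but the mean of that list moved by -0.061 ± 0.062 on the log2 scale. That was short of the fall of 0.2 set for this explanation after the values were seen. The share of erythroid cells was not measured, so a decrease too small to lower the mean by 0.2 stays open. Some members, such as Slc4a1 (mean log2 signal 15.11), lay near the highest signals of the arrays, where a fall may be understated. In the first and second array groups the list's median was 0.11 and 0.12 while each of the 289 calls kept its sign, on arrays that also chose the calls. In the third, with 7 arrays without Rb1 and 2 with it, the median was -0.29, so a larger decrease in the share of erythroid cells stays open there. Members of the list moved both ways. The list mean cannot register a change among erythroid cells that raises some members and lowers others, so it does not decide on such a change. The tables thus leave a response to Rb1 loss as a candidate explanation, as a hypothesis found and tested on the same data. Sex, which was uneven between groups, and litter or age were not tested.

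Genes near Rbl1 were over-represented among the p107 loss calls, with 12 of 279 tested genes within 20 Mb called (4.3%) against 135 of 12439 others (1.09%; Fisher's exact test, one-sided, p = 9.46e-05). They include Serinc3 (-1.92 ± 0.17), lower on 6 of 6 probe sets, Sdc4 (1.64) and Stk4 (0.45), each with a probe set of opposite sign, Pkig (-0.77) and Mybl2 (-0.39), chosen after their values were seen. A candidate explanation is DNA of another strain carried beside the mutated allele, but the labels give no strain, and opposite signs between probe sets could reflect sequence differences under a probe. The called neighbours lay at a median of 6.44 Mb from Rbl1, which argues against an effect of the allele confined to the closest genes. A local effect stays open for Ctnnbl1, at 0.533 Mb, and a 20 Mb window itself favours a distant median. Array groups as the source of the concentration are argued against by its persistence with the block (9 of 279, exact p = 9.03e-05). The exact test counts neighbouring genes as independent, which they may not be. Array groups for the single neighbours stay open, since 7 of the 12 kept call and sign with the block. Near Rb1 there was no such excess (5 of 194 against 283 of 12524, exact p = 0.449). The 5 include Xpo7, at 2.42 Mb. The test covers the neighbours as a set, so the strain explanation stays open for single ones. Near Rbl2 Arl2bp, at 3.54 Mb, was the 1 called gene (exact p = 0.0211), too few to decide.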
